A study of Homo sapiens with 10 samples.

How the data were processed

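Gene expression was measured by RNA sequencing in HUVECs at passage 3 to 5, in the 4 groups static, s-flow, siCon and siEZH2. Per the series' design text, flow was applied with a cone-and-plate device, mRNA was selected with oligo-dT beads from total RNA, libraries were made with the TruSeq RNA kit v2, and single-end reads of 100 nt were sequenced. Per the labels' protocols, the siRNAs were transfected with Lipofectamine. The static libraries have no duration in the labels. Groups and replicate numbers were taken from the sample titles, and all columns of both tables matched a sample.

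The authors deposited raw read counts per gene symbol in 2 tables, for the flow and the siRNA experiment. Per the design text and the submitters' processing notes, the authors cleaned reads with Trimmomatic 0.32, mapped them to GRCh38.p2 with STAR 2.4.2a and counted them with HTSeq 0.6.1 and the GENCODE 23 annotation. The design text also names DESeq2 1.10.1 at an adjusted p of 0.05 and Cufflinks 2.0.2 for the authors' own tests, whose results were not used here. The strand setting of the counting is not given in the sources used here. The kit does not mark strand, so reads of overlapping or antisense genes cannot be told apart, and genes with near-identical copies can share reads. Oligo-dT selection captures RNAs without a poly(A) tail, such as most histone mRNAs, poorly. The tables hold no gene with a total under 2 counts.

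The flow table held 23813 genes, of which 16946 matched GENCODE 44 by current symbol, 1054 by an older symbol and 5813 not at all. The siRNA table held 26010, with 18125, 1148 and 6737. Positions were taken from GENCODE 44 on GRCh38, a later release than the authors used. XIST, TSIX and genes of the Y chromosome were removed before any test, which left 23782 and 25985 genes.

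Each comparison was fitted on its own libraries with edgeR 4.0.16 in R 4.3.3, with TMM scaling, genes kept by filterByExpr and the robust quasi-likelihood test. Every adjusted p of a gene is Benjamini-Hochberg adjusted over the genes tested, and a gene was called at an adjusted p under 0.05. SE is the standard error of the log2 fold change, computed as its size over the square root of the F statistic. Levels are CPM with TMM-scaled library sizes. The difference between the flow and siRNA effects was tested in a single edgeR fit of all 10 libraries. The experiments were counted in separate tables, so their levels were compared only through each experiment's own controls. A fold against a group at 0 was computed against a floor of 3 counts over the group and is a lower bound that covers counting error only.

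Before the data were examined, 33 gene lists, the tests, the alternatives and the rule for named genes were fixed. The lists, drawn from general knowledge of endothelial and cell biology, were the 33 whose results are reported, markers of other cell types included. Lists with at least 5 tested members were tested with camera (limma 3.58.1, preset correlation 0.01), adjusted over the lists within a comparison, and again with an estimated correlation and with fry. The PValue of fry tests whether a set's genes move, on balance, one way, its mixed p whether they change in either direction, and neither compares the set with other genes. Overlaps of calls used Fisher's exact test, one-sided for an excess, against independent lists.

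The genes named were EZH2, 9 fixed genes (KLF2, KLF4, NOS3, THBD, EDN1, CCL2, VCAM1, IGFBP5, CDKN1A), and the 6 highest and 6 lowest fold changes among called genes with a mean of at least 1 CPM and no overlap between groups. To these were added up to 3 called members with the largest change per list, some of which are left out, and for both experiments together 6 genes higher, 6 lower and 4 of each opposite kind. Other list members, such as ACTA2, KRT7, CNN3, SLC7A11, KDR, PECAM1, FLT1, SLC2A3, BMP6, CREBBP, EP300, MTF2, KIF23, LAPTM5, PTGIS, PTGS1, ANGPT2, CXCL8, HIST1H4H and HIST1H2AC, were named after their values were seen, because they made up a small count.

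Alternatives were DESeq2 1.42.0, RLE and upper-quartile scaling, library size alone, no filter on low counts, a stricter filter (1 CPM in every library of a group and 100 counts in total), the replicate number as a block, all 10 libraries in 1 fit, a 2-fold minimum and leaving out each library in turn. For the seed analysis, the change after EZH2 siRNA was regressed on the presence of each 7-mer in the 3' UTR, with UTR length and GC content as covariates, for genes with a mean of at least 1 CPM and a UTR of at least 50 nt.

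Libraries held 21770593 to 23980260 counts, and the spread between replicates limited precision more than counting error did. The biological coefficient of variation was 18.0% in the flow and 5.24% in the siRNA experiment. Between replicates, the chi-square per gene was 30.5 for static, 77.7 for s-flow, 3.10 to 3.46 for siCon and 9.10 to 17.5 for siEZH2 libraries, where sampling noise alone gives about 1. In data simulated from the flow libraries (14161 genes in the step), the test recovered 12% of 50 genes changed by 1.5-fold, 50% at 2-fold, 94% at 4-fold and 100% at 8-fold, and 14 of its 147 calls were false. In data simulated from the siRNA libraries (14342 genes), it recovered 90%, 98%, 100% and 100%, and 22 of 253 calls were false. Few genes were changed in these simulations: 13921 of 14161 and 14102 of 14342 were unchanged. The real comparisons called far more genes, so these rates do not give their power.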

Results

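Polyadenylated RNA was sequenced from human umbilical vein endothelial cells (HUVECs), primary cells that line the vein of the umbilical cord, in 10 libraries from 2 experiments. The flow experiment had 2 libraries of cells held static and 2 libraries of cells kept for 48 h under laminar flow at a shear stress of 12 dyne per square centimetre (s-flow). The siRNA experiment had 3 libraries of cells given a control siRNA (siCon) and 3 of cells given an siRNA against EZH2 (siEZH2), each at 20 nM for 48 h. EZH2 is the catalytic subunit of Polycomb repressive complex 2 (PRC2), which places the repressive histone mark H3K27me3. The static libraries held 22154533 and 22996864 counts and the s-flow libraries 23980260 and 23905800. The siCon libraries held 21770593 to 23201659 counts and the siEZH2 libraries 21799535 to 21864264. Replicates of each group differed by more than sampling noise, so each library was counted as a sample. The labels do not say whether replicates came from separate cultures or donors, so p-values measure the spread between these samples, which may be technical.

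EZH2 was lower in every siEZH2 library than in every siCon library. It lies on chromosome 7 from 148807257 to 148884321 on the minus strand (GRCh38). Its level was 48.8 ± 0.537 CPM (read count scaled to library size; mean ± SD, n = 3) in siCon cells, between 48.3 and 49.3, and 21.5 ± 1.83 CPM (n = 3) in siEZH2 cells, between 20.1 and 23.5. This was a fall by 1.18 on the log2 scale (SE 0.0655, edgeR quasi-likelihood adjusted p = 5.33e-11). EZH2 also fell with flow, from 31.7 ± 2.89 CPM (n = 2) in static cells to 10.98 ± 2.31 CPM (n = 2) under s-flow, with a log2 fold change of -1.53 (SE 0.205, adjusted p = 0.00483). The flow effect minus the siRNA effect on EZH2 was -0.34 on the log2 scale (SE 0.170, adjusted p = 0.128), so a difference between them was not called.

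The flow comparison addressed which mRNAs differ between cells under laminar flow and static cells. KLF2 and KLF4, transcription factors known to respond to laminar shear stress, and NOS3, the endothelial nitric oxide synthase, rose under flow. KLF2 went from 21.6 ± 1.17 to 223 ± 70.5 CPM (n = 2 each; log2 fold change 3.37, SE 0.246, adjusted p = 0.00105) and KLF4 from 4.31 ± 0.120 to 103 ± 31.2 CPM (4.58, SE 0.258, adjusted p = 0.000966). NOS3 went from 75.4 ± 12.5 to 456 ± 110.05 CPM (2.60, SE 0.226, adjusted p = 0.00152). Without strand information, NOS3 reads cannot be told apart from those of ATG9B where these genes overlap. EDN1, which encodes the vasoconstrictor endothelin-1, fell from 644 ± 153 to 264 ± 132 CPM (-1.29, SE 0.373, adjusted p = 0.0472). The growth factor binding protein gene IGFBP5 rose from 3.36 ± 3.24 to 105 ± 65.4 CPM (4.97, SE 0.833, adjusted p = 0.0119). The EDN1 call was lost without static replicate 1 (adjusted p = 0.115) or static replicate 2 (0.226), with the replicate number as a block (0.0810), with no filter on low counts (0.0673) and with the stricter filter (0.0502), within a range of 0.000837 to 0.226 over all alternatives. The IGFBP5 call was lost without static replicate 2 (0.0679; range 0.000216 to 0.0679).

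Of the other genes fixed for attention, the thrombomodulin gene THBD had a log2 fold change of 1.41 with flow (SE 0.569, adjusted p = 0.113), the chemokine gene CCL2 -0.83 (SE 0.744, adjusted p = 0.428), the adhesion molecule gene VCAM1 -2.12 (SE 1.02, adjusted p = 0.160) and the cyclin-dependent kinase inhibitor gene CDKN1A 0.05 (SE 0.225, adjusted p = 0.876). None of these 4 passed the test. THBD passed without s-flow replicate 1 (log2 fold change 2.06, adjusted p = 0.000481; range over alternatives 0.000481 to 0.439), as did CCL2 (-2.56, adjusted p = 0.00355; range 0.00355 to 0.877). VCAM1, at 1.21 CPM in static cells, passed without s-flow replicate 2 (adjusted p = 0.00819; range 0.00819 to 0.510). The s-flow library left then held 0 counts of VCAM1, so the fitted fold change is no measure of size. In a fit of all 10 libraries THBD (adjusted p = 0.0408) and VCAM1 (0.0240) passed.

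**Figure D1:**
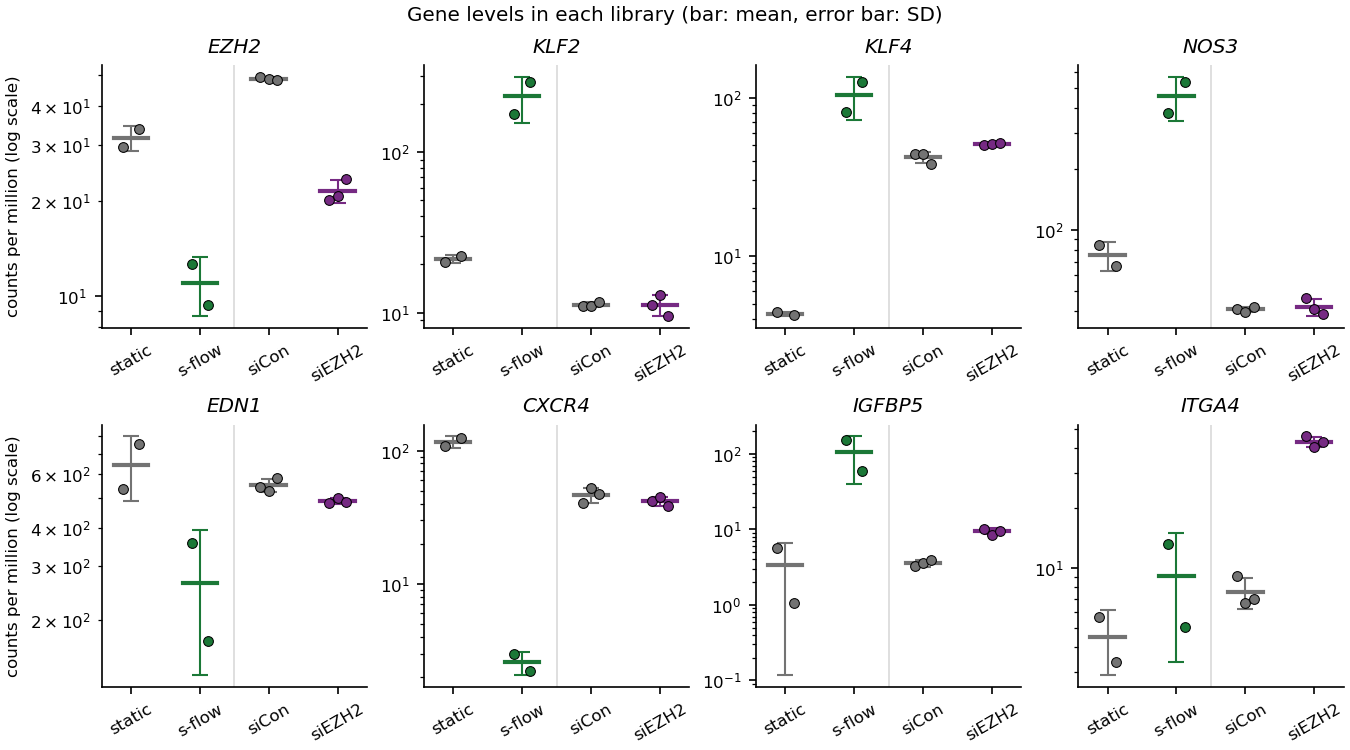
Level of 8 genes in each library, in CPM on log axes, with each point a library and the bars the mean ± SD of the static (n = 2), s-flow (n = 2), siCon (n = 3) and siEZH2 (n = 3) groups. EZH2 is lower under s-flow and after siEZH2. KLF2 rises from static to s-flow (log2 fold change 3.37) and is at the same level, 11.2 CPM, in both siRNA groups. ITGA4 goes from 7.57 CPM in siCon to 43.0 CPM in siEZH2.

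The genes with the highest fold changes under flow included the phospholipase gene PLA1A. PLA1A went from 0.507 ± 0.172 to 165 ± 3.20 CPM (log2 fold change 8.34, SE 0.229, adjusted p = 0.000196). PI16 (11.66, SE 1.54, adjusted p = 0.00656) and the neurotensin gene NTS (8.29, SE 1.51, adjusted p = 0.0138) also rose, but PI16 differed between the s-flow libraries, at 87.5 and 655 CPM. PRSS35 was at 0 in both static libraries and at least 313-fold higher under flow (adjusted p = 0.0312). The cytochrome P450 gene CYP1B1 was at least 112-fold higher (adjusted p = 0.0363), with a floor of 3 counts over the static group. Each bound pools the 2 s-flow libraries and does not show how far they differ. The calls of PI16, NTS, PRSS35 and CYP1B1 were lost without static replicate 1 (adjusted p = 0.0971, 0.115, 0.168 and 0.181) and without static replicate 2 (0.0953, 0.124, 0.164 and 0.176).

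At the other end, CHRNA1, a subunit gene of the muscle nicotinic acetylcholine receptor, went from 24.1 ± 12.1 CPM in static cells to 0 in both s-flow libraries, at least 382-fold lower (adjusted p = 0.00293). GPIHBP1, whose product anchors lipoprotein lipase on capillary endothelium, was at least 98.3-fold lower (adjusted p = 0.00842), and the collagen triple helix repeat gene CTHRC1 at least 37.9-fold lower (adjusted p = 0.00364). The netrin receptor gene UNC5A (log2 fold change -6.54, SE 0.525, adjusted p = 0.00125) and NLRP12 (-6.61, SE 0.926, adjusted p = 0.00552) fell as well. PRSS2 (-7.78, SE 0.923, adjusted p = 0.00498), a trypsinogen gene with close paralogs that can share reads, lost its call without s-flow replicate 1 (adjusted p = 0.0549; range over alternatives up to 0.0549).

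Across 14446 tested genes, 2251 were higher and 2339 lower with flow, together 31.8% of the genes, and 1216 and 1328 of these changed by at least 2-fold. Fewer genes were called when a static library was left out than when an s-flow library was. Without a static library the spread came from the s-flow pair alone, which differed more (chi-square per gene 77.7 against 30.5 for static). A call lost in such a fit need not mean that the fold change moved.

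Most genes chosen in advance as induced by laminar flow rose. Of 28 measured, 19 rose, 3 fell and 6 were not called, and adjusted over the list alone 19 rose and 4 fell. The set test camera gave an adjusted p of 3.02e-14, with a median log2 fold change of 1.88, and an adjusted p = 0.576 with an estimated correlation. Among them, the aryl hydrocarbon receptor target CYP1A1 rose from 1.99 ± 0.209 to 541 ± 155 CPM (8.08, SE 0.306, adjusted p = 0.000325). The angiopoietin receptor gene TEK rose from 181 ± 8.28 to 935 ± 99.9 CPM (2.37, SE 0.164, adjusted p = 0.00103) and the quinone reductase gene NQO1 from 44.9 ± 16.1 to 229 ± 3.74 CPM (2.35, SE 0.255, adjusted p = 0.00296). The members that fell were SEMA3G (-2.99), which encodes a semaphorin, the cystine transporter gene SLC7A11 (-1.17) and the calponin gene CNN3 (-0.66). The CNN3 call was lost without static replicate 1 (adjusted p = 0.0575), static replicate 2 (0.180) or s-flow replicate 2 (0.0506). Without static replicate 1, 13 members rose and 2 fell, and without static replicate 2, 10 rose and 2 fell.

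Genes chosen in advance as repressed by flow fell more often than they rose. Of 27 measured, 14 fell, 1 rose and 12 were not called, with 15 and 2 adjusted over the list alone (camera adjusted p = 4.0e-07, median -1.37, adjusted p = 0.576 with an estimated correlation). The chemokine receptor gene CXCR4 fell from 116 ± 11.9 to 2.59 ± 0.516 CPM (-5.48, SE 0.203, adjusted p = 0.000325). The apelin gene APLN fell from 1231 ± 534 to 58.5 ± 10.9 CPM (-4.40, SE 0.367, adjusted p = 0.00167) and the E-selectin gene SELE from 4.87 ± 2.83 to 0.466 ± 0.00676 CPM (-3.37, SE 0.535, adjusted p = 0.00795). ADAMTS18, a protease gene, was the member that rose (1.39, adjusted p = 0.00589; 0.0533 without static replicate 2). Without static replicate 1, 8 members fell, and without static replicate 2, 7 fell.

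Genes of cell division were lower under flow. All 35 measured mitosis genes fell, also adjusted over the list alone (camera adjusted p = 7.83e-59, median -3.27, adjusted p = 0.576 with an estimated correlation). KIF2C, a mitotic kinesin gene, fell from 30.1 ± 2.57 to 1.41 ± 0.728 CPM (-4.41, SE 0.344, adjusted p = 0.00121), and DLGAP5 (-4.31) and HMMR (-4.24), which encode spindle proteins, fell to a like extent. Of 38 DNA replication genes, 30 fell and 8 were not called, with 31 falling adjusted over the list alone (camera adjusted p = 2.44e-20, median -1.60, adjusted p = 0.576 with an estimated correlation). RRM2, a subunit gene of ribonucleotide reductase, fell from 104 ± 16.1 to 7.74 ± 3.99 CPM (-3.75, SE 0.371, adjusted p = 0.00280), and the replication genes GINS4 (-4.30) and MCM10 (-3.16) fell too. Of 28 cell cycle inhibitors and p53 targets, 5 rose and 4 fell, and 5 and 4 adjusted over the list alone (camera adjusted p = 0.964). Their median was -0.05 while camera's direction was up.

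The lists of histone, ribosomal protein and mitochondrial genes were called by camera under flow, but not with an estimated correlation. Of 22 listed replication-dependent histone genes, 11 had enough counts to be tested. All 11 rose, also adjusted over the list alone (camera adjusted p = 1.17e-12, median 4.19, adjusted p = 0.576 with an estimated correlation). HIST1H3H went from 0.152 ± 0.0876 to 5.41 ± 2.38 CPM (5.10, SE 0.574, adjusted p = 0.00302). Its static level lay below the low count filter, so it was tested only through its s-flow counts and could hardly have fallen. Where this holds for other members, the median and the camera p lean upward. Histone genes of this kind are near-identical copies that can share reads. The 19 with counts in the flow experiment, tested or not, took 0.000749% and 0.000922% of counts in the static libraries. They took 0.0127% and 0.00848% in the s-flow libraries. Of 40 cytosolic ribosomal protein genes, 35 fell and 5 were not called, with 39 falling adjusted over the list alone (camera adjusted p = 2.66e-12, median -0.84, adjusted p = 0.757 with an estimated correlation). Ribosomal protein mRNAs made up 3.40% and 3.66% of counts in static cells and 1.74% and 1.98% under flow. RPL3 fell from 2642 ± 149.98 to 893 ± 143 CPM (-1.57, SE 0.190, adjusted p = 0.00371). Of 13 mitochondrially encoded mRNAs, 8 rose and 5 were not called, with 9 rising adjusted over the list alone (camera adjusted p = 0.00593, median 0.70, adjusted p = 0.757 with an estimated correlation). Their share of counts was 1.94% and 1.58% in static and 2.76% and 2.36% in s-flow libraries. Without static replicate 1, 6 histone genes rose, 12 ribosomal protein genes fell and 1 mitochondrial mRNA rose, and without static replicate 2 these numbers were 5, 3 and 0.

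Camera also called the pan-endothelial and glycolysis lists under flow, but neither with an estimated correlation. Of 27 pan-endothelial genes, 9 rose, 2 fell and 16 were not called, with 11 and 4 adjusted over the list alone (camera adjusted p = 0.0407, median 0.28, adjusted p = 0.757 with an estimated correlation and 0.0963 with the replicate number as a block). TEK rose, as did PLVAP, from 7.37 ± 0.579 to 46.9 ± 3.42 CPM (2.67, SE 0.168, adjusted p = 0.000966), and MMRN2, from 477 ± 16.4 to 1952 ± 222 CPM (2.03, SE 0.173, adjusted p = 0.00143). The vascular endothelial growth factor receptor gene KDR (-0.90) and the adhesion molecule gene PECAM1 (-0.78) fell. Of 22 glycolysis genes, 11 fell, 1 rose and 10 were not called, with 12 and 1 adjusted over the list alone (camera adjusted p = 0.0131, median -0.76, adjusted p = 0.757 with an estimated correlation). PDK1, whose product inhibits pyruvate dehydrogenase, fell from 28.5 ± 6.84 to 6.10 ± 0.148 CPM (-2.23, SE 0.224, adjusted p = 0.00222), and the glucose transporter gene SLC2A3 rose (1.07). The calls of KDR, PECAM1 and SLC2A3 were lost without static replicate 1 (adjusted p = 0.074, 0.0931 and 0.0944) and without static replicate 2 (0.116, 0.296 and 0.0518), and that of PECAM1 also without s-flow replicate 1 (0.105). Without static replicate 1, 4 pan-endothelial genes rose and 6 glycolysis genes fell, and without static replicate 2, 3 rose and 1 fell.

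The other lists were not called by camera under flow. Of 24 unfolded protein and amino acid stress genes, 3 rose and 11 fell (4 and 11 adjusted over the list alone, camera adjusted p = 0.0901), the largest falls being those of PHGDH (-3.29), NUPR1 (-3.19) and ASNS (-2.35). The NUPR1 call was lost without static replicate 2 (adjusted p = 0.137) or s-flow replicate 1 (0.0633), within a range of 0.0004055 to 0.137 over all alternatives. Of 20 YAP and TEAD targets, 1 rose and 7 fell (1 and 7 adjusted over the list alone, camera adjusted p = 0.0923). Of 19 hypoxia genes, 2 rose and 5 fell (2 and 5, camera adjusted p = 0.45), with LOX at -2.39. Of 27 interferon-stimulated genes, 10 rose and 3 fell (11 and 4 adjusted over the list alone, camera adjusted p = 0.111), with CXCL11 at -6.39. Of 22 NRF2 targets, 7 rose and 4 fell (8 and 5, camera adjusted p = 0.45). Of 23 NF-kB and leukocyte adhesion genes, 5 rose and 4 fell (5 and 5 adjusted over the list alone, camera adjusted p = 0.964), and the largest rise was that of NFKBIA (3.24), an inhibitor of NF-kB. That list's median was -0.50 while camera's direction was up.

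No list of chromatin regulators or developmental genes was called by camera under flow. Of 13 PRC2 subunits, EZH2 and RBBP7 (-0.95, SE 0.125, adjusted p = 0.00456) fell and PHF1 rose (1.32, adjusted p = 0.00763; 0.0717 without static replicate 2), with 1 and 2 adjusted over the list alone (camera adjusted p = 0.455). Of 21 PRC1 subunits, 4 rose and 2 fell (4 and 2 adjusted over the list alone, camera adjusted p = 0.45). The calls of PCGF2 (1.04), PHC3 (1.02) and SCMH1 (-0.83) were lost without static replicate 2, at 0.86, 0.96 and -0.84. Of 5 H3K27 demethylases and acetyltransferases, the acetyltransferase gene CREBBP rose by 0.57 (1 adjusted over the list alone, camera adjusted p = 0.455). The CREBBP call was lost without static replicate 1 (adjusted p = 0.128), static replicate 2 (0.175) or s-flow replicate 2 (0.0515). Of 22 HOX genes tested out of 39 listed, 6 rose and 1 fell (6 and 1, camera adjusted p = 0.172). DESeq2 called 4 higher and 1 lower. The calls of HOXB9 (-1.77), HOXD3 (1.62) and HOXB5 (1.28) were lost without static replicate 1, at -1.90, 2.08 and 1.16. They were also lost without static replicate 2, at -1.67, 1.25 and 1.37. Of 88 listed developmental transcription factors often under H3K27me3, 25 were tested, of which 4 rose and 2 fell (3 and 2, camera adjusted p = 0.455). Members of these 2 lists with too few counts in both groups were not tested. Of 6 IGF binding protein genes, 3 rose and 2 fell (3 and 2, camera adjusted p = 0.884), with IGFBP3 at -2.57.

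Of 23 arterial and Notch genes, 8 rose and 5 fell under flow (8 and 6 adjusted over the list alone, camera adjusted p = 0.45), with the connexin gene GJA4 at -4.32. Of 11 venous and lymphatic genes, 3 rose (3 adjusted over the list alone, camera adjusted p = 0.109, and 0.0175 with the replicate number as a block). They were PROX1 (3.18), EPHB4 (1.29) and NR2F2 (1.04), and without static replicate 2 their calls were lost, at 2.85, 1.20 and 0.80. Of 40 basement membrane and matrix genes, 9 rose and 9 fell (12 and 9, camera adjusted p = 0.842). The protease gene ADAMTS1 went from 27.3 ± 15.2 to 1969 ± 133 CPM (6.17, SE 0.462, adjusted p = 0.00137). Of the 27 endothelial-to-mesenchymal and contractile genes, 4 rose and 6 fell (4 and 8, camera adjusted p = 0.842). S100A4 (5.06) and ID1 (2.39) rose and the myosin light chain gene MYL9 (-1.94) fell. The list's mean was 0.14 while its median was -0.17. Of 20 immediate early genes, 6 rose and 4 fell (6 and 5, camera adjusted p = 0.45), with EGR1 at -3.54 and EGR2 at least 7.59-fold lower. The mean of this list was -0.08 while the median was 0.41. Of 30 axon guidance genes, 7 rose and 7 fell (7 and 7, camera adjusted p = 0.842). Of 24 cholesterol synthesis genes, 3 rose and 3 fell (3 and 1, camera adjusted p = 0.879). Of 8 smooth muscle and fibroblast markers, 1 rose and 2 fell (1 and 2, camera adjusted p = 0.964), with a mean of -0.63 and a median of 0.05. The calls of COL3A1 (1.75), LUM (-4.43) and DCN (-3.18) were lost without static replicate 2, at 1.61, -3.86 and -2.20. KRT7 (-3.32) was the 1 of 4 epithelial markers that fell. The 2 leukocyte markers tested were not called, and no erythroid marker was tested.

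**Figure D2:**
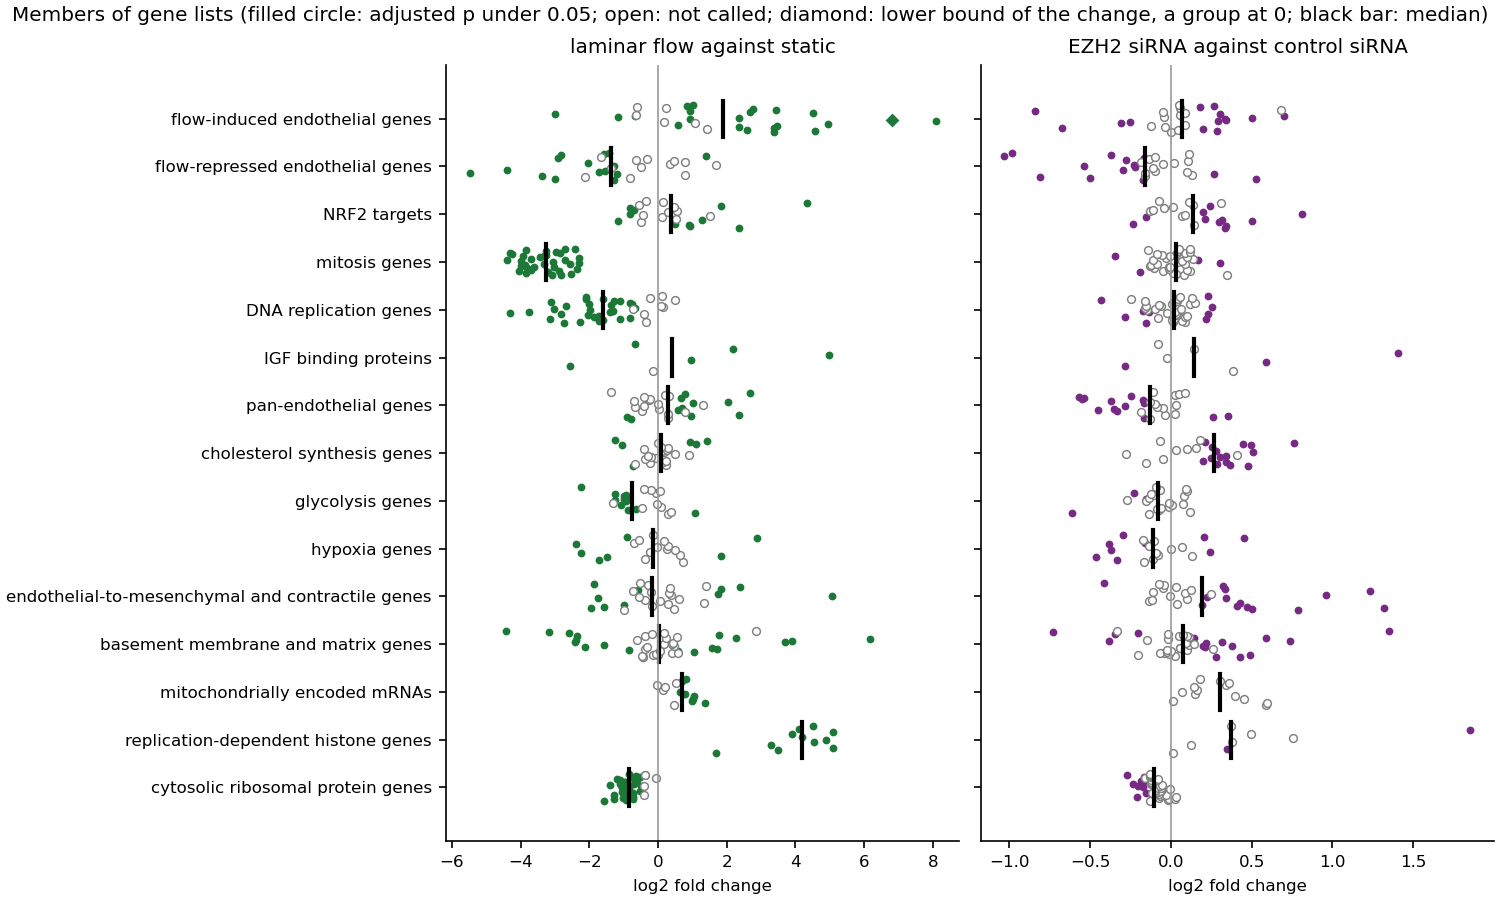
Log2 fold changes of the tested members of the 15 lists that camera called in either comparison, with s-flow against static (n = 2 each) and siEZH2 against siCon (n = 3 each) side by side, a point for each gene and a black bar at the list's median. The mitosis genes have a median of -3.27 under flow and 0.03 after EZH2 siRNA, and the cholesterol synthesis genes 0.09 and 0.27.

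The siRNA comparison addressed which mRNAs change when EZH2 is lowered in cells that were not under flow. ITGA4, the integrin alpha-4 gene, rose from 7.57 ± 1.34 to 43.0 ± 2.58 CPM (n = 3 each; log2 fold change 2.50, SE 0.0934, adjusted p = 2.67e-12). MET, the hepatocyte growth factor receptor gene, rose from 59.4 ± 3.62 to 167 ± 6.07 CPM (1.49, SE 0.0539, adjusted p = 1.86e-13). CERKL rose from 1.22 ± 0.228 to 8.03 ± 0.443 CPM (2.72, SE 0.154, adjusted p = 7.22e-11). ITGA4 (chromosome 2, 181457202 to 181538940, plus strand) and CERKL (181535041 to 181680665, minus strand) overlap at their ends, so their counts cannot be told apart there. EPPK1 (2.24, SE 0.344, adjusted p = 0.000564), the chemokine gene CXCL6 (2.03, SE 0.272, adjusted p = 1.71e-05) and MYEOV (1.56, SE 0.274, adjusted p = 0.000345) rose from below 1 CPM.

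The P-selectin gene SELP had the lowest fold change after EZH2 siRNA among called genes that averaged at least 1 CPM and did not overlap between groups, from 6.74 ± 1.27 to 2.17 ± 0.475 CPM (-1.64, SE 0.176, adjusted p = 2.94e-06). It was followed by the mitochondrial ribosomal protein gene MRPS9, from 19.0 ± 0.787 to 6.13 ± 0.458 CPM (-1.63, SE 0.0890, adjusted p = 4.46e-11), and ACKR4, an atypical chemokine receptor gene (-1.46, SE 0.249, adjusted p = 0.000254). The syntaxin gene STX12 fell from 109 ± 1.97 to 41.9 ± 2.54 CPM (-1.38, SE 0.0539, adjusted p = 2.94e-13) and IGF2BP3, an RNA-binding protein gene that overlaps MALSU1, from 97.8 ± 3.66 to 37.95 ± 1.2501 CPM (-1.36, SE 0.0533, adjusted p = 2.94e-13). ANKRD46 also fell (-1.28, SE 0.140, adjusted p = 5.6e-06). EZH2 itself had a log2 fold change of -1.18.

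Of the genes fixed for attention, KLF2, NOS3 and CDKN1A were not called after EZH2 siRNA. KLF2 was at 11.2 ± 0.397 and 11.2 ± 1.62 CPM (log2 fold change 0.00, SE 0.0992, adjusted p = 0.999) and NOS3 at 40.8 ± 0.993 and 42.0 ± 4.09 CPM (0.04, SE 0.0657, adjusted p = 0.702). The flow effect exceeded the siRNA effect on KLF2 by 3.37 (SE 0.265, adjusted p = 7.01e-06), on NOS3 by 2.55 (SE 0.214, adjusted p = 6.17e-06) and on KLF4 by 4.30 (SE 0.235, adjusted p = 2.95e-07). The effects also differed for IGFBP5 (adjusted p = 0.0142) and EDN1 (0.0426). No difference was called for THBD (0.161), CCL2 (0.775), VCAM1 (0.209) and CDKN1A (0.851). These differences come from the fit of all 10 libraries, where the shared estimate of the spread may make their p-values too small. KLF4 rose by 0.28 after EZH2 siRNA (SE 0.0616, adjusted p = 0.00218) and THBD by 0.20 (SE 0.0496, adjusted p = 0.00603). CCL2 fell from 169 ± 10.1 to 119.75 ± 6.85 CPM (-0.50, SE 0.0544, adjusted p = 1.25e-06) and VCAM1 from 5.64 ± 0.328 to 3.20 ± 0.288 CPM (-0.81, SE 0.132, adjusted p = 0.000151). IGFBP5 rose from 3.55 ± 0.333 to 9.44 ± 0.863 CPM (1.41, SE 0.120, adjusted p = 4.06e-08), and CDKN1A had a log2 fold change of -0.00 (SE 0.0487, adjusted p = 0.979). In the fit of all 10 libraries the siRNA calls of KLF4 (adjusted p = 0.309), THBD (0.858), CCL2 (0.701), VCAM1 (0.258) and IGFBP5 (0.271) were lost. EDN1 fell by 0.17 (SE 0.0502, adjusted p = 0.0195), a call lost without siCon replicate 1 (adjusted p = 0.0509) or siCon replicate 3 (0.168) or with the replicate number as a block (0.0583), with 0.799 the highest over all alternatives.

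Across 14515 tested genes, 1596 were higher and 1375 lower after EZH2 siRNA, together 20.5%, with a median change of 1.22-fold, and 83 and 47 of these changed by at least 2-fold. With scaling by library size alone, 1220 were higher and 1871 lower, so the share of higher genes among the calls was 39.5% against 53.7%. Without siCon replicate 3, 1069 were higher and 854 lower, and in a fit of all 10 libraries, which takes in the wider spread of the flow libraries, 202 and 179.

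Most genes of cholesterol synthesis rose after EZH2 siRNA. Of 24 measured, 15 rose and 9 were not called, with 16 rising adjusted over the list alone (camera adjusted p = 2.08e-09, median 0.27, adjusted p = 0.0833 with an estimated correlation). INSIG1, a regulator of the pathway, rose from 36.1 ± 0.710 to 61.2 ± 2.92 CPM (0.76, SE 0.0562, adjusted p = 4.73e-09), and the enzyme gene MSMO1 (0.51, SE 0.0526) rose with it.

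Camera called the endothelial-to-mesenchymal and contractile list upward and the pan-endothelial list downward after EZH2 siRNA, but neither with an estimated correlation. Of 27 genes of the first kind, 13 rose, 1 fell and 13 were not called, with 13 and 1 adjusted over the list alone (camera adjusted p = 7.52e-09, median 0.19, adjusted p = 0.336 with an estimated correlation). The calponin gene CNN1 rose from 4.49 ± 0.519 to 11.2 ± 1.00 CPM (1.32, SE 0.113, adjusted p = 4.04e-08). TGFBI, a matrix protein gene induced by TGF-beta, rose from 85.5 ± 2.30 to 201 ± 10.5 CPM (1.24, SE 0.0511, adjusted p = 6.72e-13) and the collagen gene COL1A2 from 9.61 ± 1.20 to 18.7 ± 2.42 CPM (0.96, SE 0.104, adjusted p = 4.35e-06). BMP6 fell (-0.41). Of 27 pan-endothelial genes, 12 fell, 2 rose and 13 were not called, with 14 and 2 adjusted over the list alone (camera adjusted p = 1.12e-05, median -0.13, adjusted p = 0.398 with an estimated correlation). ICAM2 (-0.57, SE 0.0494), SOX18 (-0.55, SE 0.0574) and SOX7 (-0.54, SE 0.0558) fell, and the receptor genes FLT1 (0.35) and KDR (0.26) rose. The KDR call was lost without siCon replicate 1 (adjusted p = 0.0681), siCon replicate 3 (0.0595) or siEZH2 replicate 1 (0.0827). Of 10 smooth muscle and fibroblast markers, which share ACTA2, COL1A2 and CNN1 with the contractile list, 3 rose and 2 fell (3 and 2 adjusted over the list alone, camera adjusted p = 0.128). The ACTA2 call was lost without siCon replicate 1 (adjusted p = 0.0870), siCon replicate 3 (0.0820) or siEZH2 replicate 1 (0.0637), and with DESeq2 (0.0592). Of 4 epithelial markers, KRT7 fell (-0.55), with 2 falling adjusted over the list alone. The 1 leukocyte marker tested, LAPTM5, rose by 0.23, and no erythroid marker was tested.

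Among genes chosen as repressed by flow, 12 of 27 fell after EZH2 siRNA, 2 rose and 13 were not called, with 14 and 2 adjusted over the list alone (camera adjusted p = 6.38e-06, median -0.16, adjusted p = 0.336 with an estimated correlation). ADAMTS18 fell from 80.4 ± 6.94 to 39.3 ± 2.79 CPM (-1.03, SE 0.0671, adjusted p = 4.37e-09) and INHBA, an activin subunit gene, from 60.5 ± 5.68 to 30.7 ± 0.286 CPM (-0.98, SE 0.0657, adjusted p = 9.56e-10). ANGPT2 (0.53) and CXCL8 (0.27) rose. Of 26 genes chosen as induced by flow, 10 rose, 4 fell and 12 were not called, with 10 and 4 adjusted over the list alone (camera adjusted p = 0.0296, median 0.07, adjusted p = 0.389 with an estimated correlation). Those that fell were the hedgehog ligand gene DHH (-0.84), the argininosuccinate synthase gene ASS1 (-0.68), PTGIS (-0.31) and PTGS1 (-0.25), both of prostanoid synthesis. The PTGIS call was lost without any of siCon replicates 1 (adjusted p = 0.113), 2 (0.0623) and 3 (0.183) and without siEZH2 replicate 3 (0.172). It was also lost with DESeq2 (0.0862) and with the replicate number as a block (0.069).

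Of 22 NRF2 targets, 9 rose, 2 fell and 11 were not called, with 9 and 3 adjusted over the list alone (camera adjusted p = 0.00792, median 0.14, adjusted p = 0.440 with an estimated correlation). The transporter gene ABCC3 (0.81), SLC7A11 (0.50) and the heme oxygenase gene HMOX1 (0.34) were among those that rose. Of 7 IGF binding protein genes, IGFBP5 and IGFBP3 (0.59) rose and IGFBP2 (-0.28) fell, with 2 and 1 adjusted over the list alone (camera adjusted p = 0.0324, median 0.14, adjusted p = 0.389 with an estimated correlation). That median was 0.01 without siCon replicate 3, 0.03 without siCon replicate 2 and 0.30 without siCon replicate 1. Of 39 basement membrane and matrix genes, 12 rose and 4 fell, with 12 and 5 adjusted over the list alone (camera adjusted p = 0.0324, median 0.08, adjusted p = 0.668 with an estimated correlation). The median was -0.00 without siEZH2 replicate 1. The proteoglycan gene VCAN rose from 9.66 ± 0.128 to 24.7 ± 6.22 CPM (1.35, SE 0.198, adjusted p = 0.00605). Of 19 hypoxia genes, 6 fell and 3 rose, with 8 and 4 adjusted over the list alone (camera adjusted p = 0.0296, median -0.11, adjusted p = 0.336 with an estimated correlation). BNIP3 (-0.47) and LOX (-0.39) were among those that fell.

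Of 40 cytosolic ribosomal protein genes, 9 fell and 31 were not called, also adjusted over the list alone (camera adjusted p = 0.00177, median -0.10, adjusted p = 0.668 with an estimated correlation), with RPS28 at -0.27. The number that fell was 2 without siCon replicate 1, 3 without siCon replicate 3, 5 without siEZH2 replicate 3 and 16 without siEZH2 replicate 2. Their share of counts was 3.45% to 3.69% in siCon and 3.09% to 3.47% in siEZH2 libraries. Of 13 mitochondrially encoded mRNAs, edgeR called 0, and 0 passed at an unadjusted p under 0.05 or by DESeq2 (camera adjusted p = 0.467). The library siEZH2 replicate 3 held 3.49% mitochondrial counts against 1.83% and 1.66% in the other siEZH2 libraries. Of 8 replication-dependent histone genes, HIST1H4H (1.86) and HIST1H2AC (0.35) rose, 2 also adjusted over the list alone (camera adjusted p = 0.0739). The HIST1H2AC call was lost without siCon replicate 2 (adjusted p = 0.188) or 3 (0.187) and without siEZH2 replicate 2 (0.161) or 3 (0.0517). It was also lost with DESeq2 (0.134) and with the replicate number as a block (0.0631). DESeq2 called 0 of the 8 genes higher, and with all 10 libraries in 1 fit HIST1H4H was not called (adjusted p = 0.109).

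Cell cycle genes were not called as lists after EZH2 siRNA. Of 35 mitosis genes, CENPF (0.31) and KIF23 (0.17) rose and BIRC5 (-0.35) and CDK1 (-0.19) fell, with 2 falling adjusted over the list alone (camera adjusted p = 0.869). The CENPF call was lost without siCon replicate 1 (adjusted p = 0.147), 2 (0.103) or 3 (0.116) or siEZH2 replicate 3 (0.0721), and that of CDK1 without siCon replicate 1 (0.0849) or 3 (0.109) or siEZH2 replicate 1 (0.0525). The KIF23 call was lost without siCon replicate 1 (0.107), 2 (0.118) or 3 (0.0587) or siEZH2 replicate 1 (0.095) or 3 (0.0511). It was also lost with DESeq2 (0.0783) and with the replicate number as a block (0.0505). Of 38 DNA replication genes, 4 rose and 5 fell (4 and 6 adjusted over the list alone, camera adjusted p = 0.896), with a median of 0.02 and a mean of -0.01. For KIF2C the flow effect minus the siRNA effect was -4.29 on the log2 scale (SE 0.260, adjusted p = 3.54e-07). Of 28 cell cycle inhibitors and p53 targets, 2 rose and 3 fell (2 and 3, camera adjusted p = 0.137).

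Those genes of chromatin regulation and development that were tested were mostly not called after EZH2 siRNA. Of 13 PRC2 subunits, EZH2 fell and MTF2 (0.22) rose (1 and 1 adjusted over the list alone, camera adjusted p = 0.351), with a median of 0.00 and a mean of -0.06. Of 21 PRC1 subunits, 1 rose and 3 fell (1 and 2, camera adjusted p = 0.409), led by PCGF6 (-0.51) and RNF2 (-0.30). CREBBP (0.18) and EP300 (0.29), both acetyltransferases, rose among 5 H3K27 demethylases and acetyltransferases (2 adjusted over the list alone, camera adjusted p = 0.229). The calls of MTF2, CREBBP and EP300 were lost without siCon replicate 1 (adjusted p = 0.0842, 0.1185 and 0.135) or 3 (0.0554, 0.104 and 0.0770). Those of MTF2 and EP300 were also lost without siCon replicate 2 (0.0565 and 0.0713) or siEZH2 replicate 3 (0.0536 and 0.0694), that of MTF2 without siEZH2 replicate 2 (0.0666) and that of CREBBP without siEZH2 replicate 1 (0.1202). With DESeq2 neither MTF2 (adjusted p = 0.0761) nor CREBBP (0.0501) was called, and with all 10 libraries in 1 fit none of the 3 was (0.298, 0.306 and 0.206). CREBBP was also not called with the replicate number as a block (0.0556). Of 24 HOX genes tested out of 39 listed, 3 fell and 21 were not called (3 adjusted over the list alone, camera adjusted p = 0.234). They were HOXA5 (-0.41), HOXA10 (-0.36) and HOXB7 (-0.25), and without siCon replicate 1 the adjusted p of HOXA5 was 0.0525 and of HOXA10 0.0719. Without siEZH2 replicate 1 that of HOXA10 was 0.0557 and of HOXB7 0.0685, and HOXB7 was also not called without siCon replicate 2 (0.0660) or 3 (0.102) or siEZH2 replicate 3 (0.0971). With DESeq2, which called 1 HOX gene lower, HOXA10 (0.0710) and HOXB7 (0.0712) were not called, and with all 10 libraries in 1 fit none of the 3 was (0.145, 0.114 and 0.206). Of 88 listed developmental transcription factors often under H3K27me3, 26 were tested. SNAI1 (0.43) rose and 4 fell (1 and 4, camera adjusted p = 0.424). Members of both lists with too few counts in both groups were left out, so silent genes were not tested.

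The remaining lists were not called by camera after EZH2 siRNA. Of 26 NF-kB and leukocyte adhesion genes, 8 rose and 3 fell (8 and 3 adjusted over the list alone, camera adjusted p = 0.201), with CX3CL1 at 0.78 and SELP, CCL2 and VCAM1 the members that fell. Of 28 interferon-stimulated genes, 7 fell and 21 were not called (7 adjusted over the list alone, camera adjusted p = 0.0687), with IFI6 at -0.69 and IRF7 at -0.49. Of 22 glycolysis genes, 3 fell and 19 were not called (2, camera adjusted p = 0.0687). Of 24 arterial and Notch genes, 3 rose and 6 fell (4 and 10, camera adjusted p = 0.409), with the Notch ligand gene JAG1 at 0.71 (SE 0.0483, adjusted p = 1.28e-09) and HEY1 at 0.58. Of 11 venous and lymphatic genes, 3 rose and 2 fell (3 and 2, camera adjusted p = 0.894), with a mean of 0.10 and a median of -0.04. Of 20 YAP and TEAD targets, 5 rose and 5 fell (6 and 6, camera adjusted p = 0.922). Of 20 immediate early genes, 5 rose and 2 fell (5 and 2, camera adjusted p = 0.424, mean 0.06 and median -0.00). Of 24 unfolded protein and amino acid stress genes, 3 rose and 2 fell (3 and 2, camera adjusted p = 0.894). Of 31 axon guidance genes, 8 rose and 8 fell (8 and 8, camera adjusted p = 0.764).

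Flow and EZH2 siRNA were then compared gene by gene, since the study set the flow profile beside one that depends on EZH2. IGFBP5, SELPLG and ATP2A3 rose in both experiments and IGF2BP3, MGARP and RCAN2 fell in both, as did EZH2. SELPLG, the gene of the P-selectin ligand, had log2 fold changes of 3.37 with flow and 1.08 with siRNA, and ATP2A3, a calcium pump gene, of 4.68 and 1.15. IGF2BP3 had -1.38 (SE 0.183) and -1.36 (SE 0.0533), a difference of -0.01 (SE 0.161, adjusted p = 0.963). MGARP had -2.39 and -0.94, and RCAN2, a calcineurin regulator gene, -5.47 and -1.14.

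Among the other genes that led these groups, some flow calls were lost when a library was left out. ZNF385A (1.11 and 1.10), ZDHHC11 (2.97 and 1.00), the fibrillin gene FBN1 (1.94 and 0.91), the pseudogene RPL15P3 (-1.54 and -1.03), whose counts may include reads of its parent gene, and INHBA (-1.42 and -0.98) were called in both. Without static replicate 1 their adjusted p under flow was 0.0538, 0.0514, 0.105, 0.128 and 0.179, and without static replicate 2 it was 0.130, 0.0524, 0.0991, 0.0890 and 0.0617. INHBA was also not called without s-flow replicate 2 (0.157), and the siRNA call of FBN1 was lost without siCon replicate 1 (0.0826), 2 (0.0770) or 3 (0.0771) or siEZH2 replicate 3 (0.0598).

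Other genes moved in opposite directions. The heparan sulfate sulfatase gene SULF1 rose with flow and fell with siRNA (3.55 and -0.95, difference 4.50, SE 0.221, adjusted p = 1.63e-07), as did NYAP1 (1.71 and -0.87, adjusted p of the difference 2.98e-06), ACKR4 (1.94 and -1.46, 0.000539) and ADAMTS18 (1.39 and -1.03, 2.91e-06). The cyclin gene CCNA1 fell with flow and rose with siRNA (-5.37 and 1.49, difference -6.86, SE 0.310, adjusted p = 6.12e-08), as did the deiodinase gene DIO2 (-4.66 and 1.17, 8.66e-07), CDCP1 (-1.77 and 1.03, 0.000419) and DPYSL3 (-1.37 and 0.92, 1.21e-05). The flow calls of ACKR4, CDCP1 and DPYSL3 were lost without static replicate 1 (adjusted p = 0.148, 0.119 and 0.0512) and without static replicate 2 (0.100, 0.0731 and 0.0696), and that of ADAMTS18 without static replicate 2 (0.0533).

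**Figure D3:**
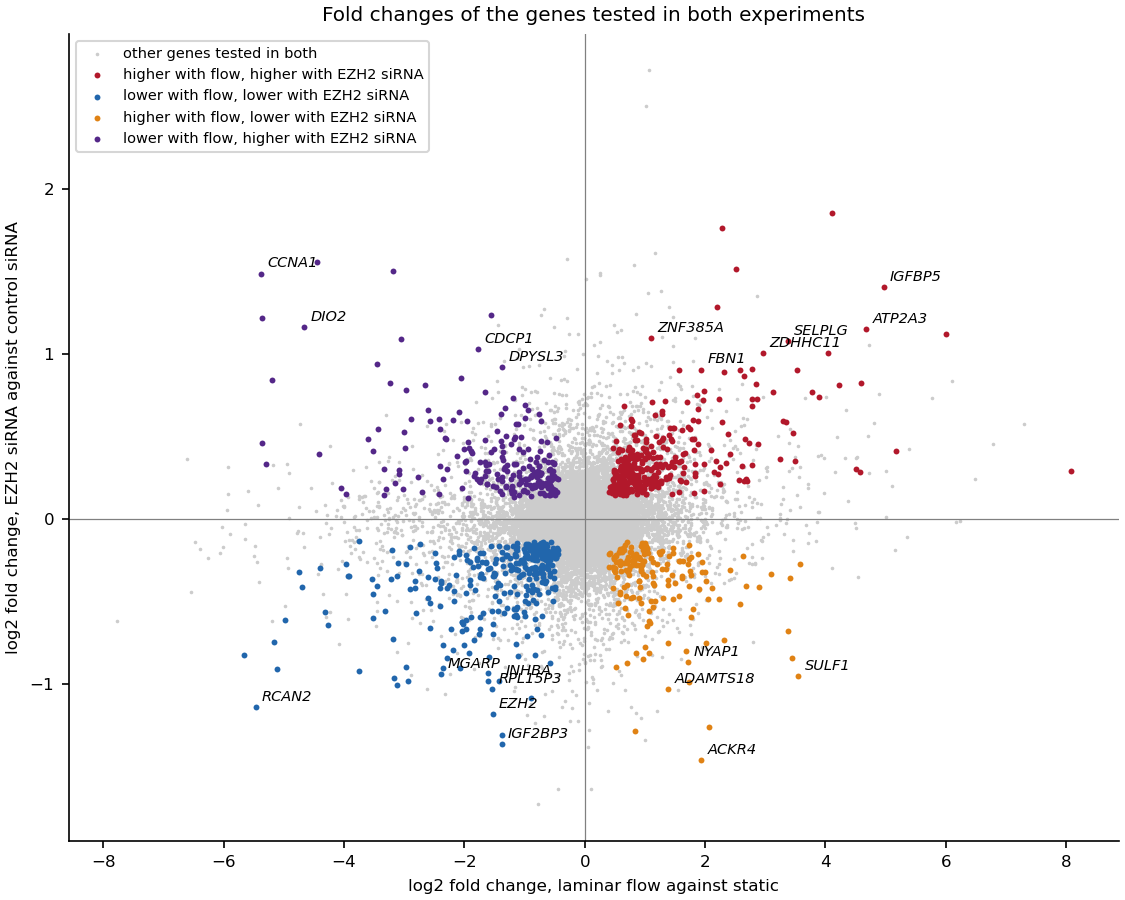
Log2 fold change with flow (s-flow against static, n = 2 each) on the horizontal axis and with EZH2 siRNA (siEZH2 against siCon, n = 3 each) on the vertical axis, a point per gene tested in both, with genes called in both coloured by direction and genes with a group at 0 left out. Across genes Pearson's r is 0.15, and 345 genes are higher and 329 lower in both experiments.

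Of 13754 genes tested in both experiments, 345 were higher in both against 226 expected from independent lists (ratio 1.53, Fisher's exact test, one-sided, p = 3.68e-18), and 329 were lower in both against 226 expected (ratio 1.45, p = 3.15e-14). Fisher's test counts genes as independent, which they are not. Its p-values do not measure the spread between libraries and may be far too small. Opposite changes numbered 168 genes higher with flow and lower with siRNA against 201 (ratio 0.838) and 222 lower with flow and higher with siRNA against 255 (ratio 0.871). A deficit was not tested, and the ratios differed between alternatives. In the same order, the 4 ratios were 2.62, 2.55, 1.34 and 1.46 with DESeq2 and 2.27, 2.26, 1.18 and 1.24 with no filter, both over 22358 genes. Both backgrounds hold many genes with few counts. DESeq2 gave no adjusted p to 7838 of 23782 genes with flow and 12595 of 25985 with siRNA, which were counted as not called. Genes that could hardly be called raise all 4 ratios, so these are not comparable with those over 13754 genes. They were 1.27, 1.53, 1.02 and 1.19 in a fit of all 10 libraries and 3.05, 1.75, 1.12 and 1.94 with a 2-fold minimum, and without static replicate 2 the last was 1.32. Across genes, which are not independent replicates, the log2 fold changes had a Pearson's r of 0.15 and a Spearman's rho of 0.15. Among the 1064 genes called in both r was 0.23, with 63.3% of the same sign. Without static replicate 1 the 4 overlaps were 115, 138, 54 and 87 genes, and without static replicate 2 they were 60, 87, 30 and 86. Without siCon replicate 3, 204 genes were lower in both and 110 higher with flow and lower with siRNA, and without siCon replicate 1, 146 were lower with flow and higher with siRNA.

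As sets, the 1360 genes lower after EZH2 siRNA had a median log2 fold change of -0.17 under flow, with 40.3% above 0 against 50.3% of all genes (camera p = 0.0200, 0.229 with an estimated correlation, fry p = 0.0362). The 1532 genes higher after EZH2 siRNA had a median of 0.11 under flow, with 57.1% above 0 (camera p = 0.0828, 0.536 with an estimated correlation, fry p = 0.194). In the siRNA comparison, the 2028 genes higher with flow had a median of 0.04, with 59.7% above 0 against 49.3% of all genes (camera p = 0.0200, 0.226 with an estimated correlation, fry p = 0.0412). The 2288 lower with flow had a median of -0.04, with 40.7% above 0 (camera p = 0.0624, 0.198 with an estimated correlation, fry p = 0.0184). With camera, the call of the genes lower after siRNA was lost without s-flow replicate 1 (0.0525) and that of the genes higher with flow without siEZH2 replicate 1 (0.0733). The genes higher after siRNA passed without static replicate 1 (0.0228) or s-flow replicate 1 (0.0418). The genes lower with flow passed without siCon replicate 2 (0.0423) or siEZH2 replicate 2 (0.0178). The flow and siRNA effects differed for 6235 of 15454 genes in a fit of all 10 libraries. The flow effect lay above the siRNA effect for 2959 and below it for 3276. This fit takes 1 spread for both experiments, although their biological coefficients of variation were 18.0% and 5.24%, so the number may be too high.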

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

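The counts without genes that carry the 6-mers GACAGT or GACGTA in the 3' UTR, and those without the cell cycle lists, were chosen after the data were seen. Changed genes numbered 4046 higher and 4179 lower with flow and 202 and 179 with EZH2 siRNA in a fit of all 10 libraries, where both experiments share 1 estimate of the spread, and the overlaps were 67 higher in both, 74 lower in both, 48 higher with flow and lower with siRNA, and 65 the reverse. With a 2-fold minimum, which removes smaller changes by construction, the counts were 1216 and 1328 with flow, 83 and 47 with siRNA, and 11, 6, 3 and 9 in the overlaps. Leaving out each library in turn gave 356 to 2535 genes higher and 593 to 2568 lower with flow, and 1069 to 1524 higher and 854 to 1371 lower with siRNA, where a lone static or s-flow library is assumed to vary like the other group. The overlaps ranged over 60 to 360, 87 to 369, 30 to 185 and 86 to 246 genes, and the correlation of fold changes over 0.126 to 0.185, and it was 0.126 among genes of at least 10 CPM. The camera p under flow ranged over 0.0228 to 0.563 for genes higher after siRNA and 0.00393 to 0.0525 for genes lower, and after siRNA over 0.00263 to 0.0733 for genes higher with flow and 0.0178 to 0.171 for genes lower. With an estimated correlation the p was 0.229 for genes lower after siRNA and 0.226 for genes higher with flow, and fry gave 0.0184 for genes lower with flow. Fewer genes counted gave 779 genes lower after siRNA without carriers of GACAGT, and overlaps of 216, 207, 83 and 139 without carriers of either 6-mer, which were 1.58, 1.60, 0.760 and 0.860 times the number expected. The overlap without the cell cycle lists was 323 genes lower in both, but the lists held only 6 of the 329 and so could not test it. Apart from these fewer libraries or genes, the cause was not tested.

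DESeq2, the other scalings and both filters kept each count of changed genes within 1.5 times, and EZH2 was called lower under every alternative, between -1.76 and -1.33 with flow and between -1.25 and -1.14 with siRNA on leaving out a library. Of 117 genes named for flow, 61 lost their call when some library was left out, 8 with no filter and 2 with DESeq2. Of 104 named for siRNA, 21 lost it on leaving out a library and 11 with DESeq2, and of 103 in the fit of all libraries 64 lost it. No named gene that was called reversed. All 9 lists that camera called with flow and all 10 with siRNA lost the call with an estimated correlation. With fry, all 9 with flow and 2 with siRNA lost it, and fry called 2 others with siRNA. With the replicate number as a block, 2590 genes were higher and 2732 lower with flow and 1379 and 1173 with siRNA, 1 list call with flow was lost and 1 gained, and none changed with siRNA. Same-numbered siRNA libraries deviated from their group means with correlations of -0.06, -0.08 and -0.00. In the flow experiment the value was 0.17 for same-numbered libraries and -0.17 for the others, equal in size by construction with 2 per group. Pairing there stays open. The labels do not say that a number marks a shared culture, so the numbers were not taken to pair the samples. Depth limits genes near 1 CPM, and the flow experiment is also limited by its 2 libraries per group and its wider spread between replicates.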

Other observations

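The test of S phase for the histone genes, the tests of the genes lower in both experiments and of EZH2 among replication genes were chosen after the results were seen.

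Part of the genes that changed after EZH2 siRNA carried short shared sequences in their 3' UTRs. In a regression over 11655 genes and 16181 sequences of 7 bases, 12 passed with carriers shifted down and 4 with carriers shifted up. Among the 12, GGACAGT had the lowest t and the largest shift, -0.0801 on the log2 scale (1441 carriers, Bonferroni adjusted p = 1.44e-25), while a sequence that did not pass shifted by more (0.0896 in size). Of the 12, 7 contain GACAGT, and a seed with that core does not account for the other 5. Of these, TGGCTAA and GGCTAAT overlap, so the 5 need not be separate signals, and their source was not tested. GGACAGT also occurs in the EZH2 mRNA, as do 6 of the 12 in all and 13.9% of those tested, and 46.7% of the genes called lower carried GACAGT against 30.3% of those not called. The 4 that passed upward all contain GACGTA. TGACGTA had the highest t, with a shift of 0.114 (189 carriers, Bonferroni adjusted p = 1.46e-06), and GACGTAA and GACGTAC shifted further, by 0.129 and 0.135. The shift of TGACGTA exceeded in size that of every sequence that shares no run of 5 bases with it (0.0896 at most), and 11.9% of the genes called higher carried GACGTA against 3.73%. A candidate explanation is that part of the genes called lower match the seed of the EZH2 siRNA. IGF2BP3, STX12, ANKRD46 and INHBA, for example, carry GACAGT. In the same way, part of the genes called higher may have been lowered in control cells by the control siRNA. By raw shares of carriers, the excess was about 207 of 1259 genes for GACAGT and 122 of 1492 for GACGTA. For GGACAGT it was about 135 of 1259. These numbers are not adjusted for UTR length or GC content, so they are no count of seed effects. The siRNA sequences were not used here, MRPS9 and SELP carry no GACAGT and IGFBP5 rose despite carrying it, loss of EZH2 stays open for the rest, and with 10 splits of the 6 libraries the share with as many changed genes (1, the real split, with 2971 genes against 0 at most in the others) cannot fall under 0.05.

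All 11 replication-dependent histone mRNAs tested, of 22 listed, rose with flow, though some could hardly have fallen given the low count filter. Of 38 genes of DNA replication, 30 fell and 8 were not called. Neither list was called by camera with an estimated correlation (adjusted p = 0.576 for each). More RNA without a poly(A) tail in the flow libraries would also raise other such RNAs, but RMRP, RN7SK and RPPH1 had a median log2 fold change of -0.15 (SE 0.822), below 2.10, 50% of the histone median of 4.19. More cells in S phase would raise the DNA replication genes, whose median was -1.60 (SE 0.228). The values of the DNA replication genes argue against more cells in S phase. Polyadenylated histone transcripts in cells that leave the cycle may also account for the pattern, a hypothesis that was not tested.

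Genes lower in both experiments, EZH2 among them, could reflect a shared fall of cell cycle genes. After EZH2 siRNA the 73 mitosis and DNA replication genes had a median log2 fold change of 0.0212 (SD 0.142), above -0.1499, 50% of the median of -0.2998 of the 329 genes lower in both, by more than that SD. The 329 were selected for falling after siRNA, so this mark lies below 0 by construction, and lying above it decides nothing. The values show only that the 73 listed genes did not fall as a set after siRNA. For part of the genes the explanation stays open, since 6 of the 73 were among the 329. For EZH2 under flow, a fall along with cell cycle genes and an effect of flow on EZH2 apart from the cell cycle cannot be told apart. Its log2 fold change of -1.53 lay within the range of the 30 called DNA replication genes, -4.30 to -0.66, but so did 79.5% of all genes called lower, so the range decides nothing.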
